A study of Mus musculus with 5 samples.

How the data were processed

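Gene expression was measured in tissue dissected from wild-type mouse embryos at E10.5, a piece that held the pharyngeal arches and, per the labels, the second heart field, the progenitor population that adds muscle to the outflow and inflow poles of the heart. There were 5 samples, each a separate tissue isolate, and all belonged to 1 group. The mice came from the strain 129P2/OlaHsd crossed back to C57BL/6 for 2 generations. Per the labels' protocols, RNA was extracted with Trizol and column purification, and 10 ng of total RNA per sample was amplified and biotin-labelled with NuGEN Ovation kits before hybridisation to an Affymetrix Mouse Genome 430A array. Such amplification starts from very little RNA, and differences in amplification between samples are part of the spread between them. The labels do not say whether the isolates came from different litters.

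The deposited values were intensity values, 1 signal per probe set and array, on a linear scale. Per the submitters' processing notes the software was GCOS (Affymetrix's operating software), with its version, algorithm and settings not given in the sources used here. The deposited intensity values carried a trace of the scaling: after leaving out the lowest and highest 2% of probe sets, the mean signal of every array lay at 150.1. No present or absent calls and no raw probe intensities were used here, so detection had to be judged from the signals themselves.

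The table held 22690 probe sets, of which 64 were control probe sets and were left out of every gene test. Of the other 22626 probe sets, 20380 were annotated with 1 gene, 691 with several genes and 1555 with none in the annotation used here, and no gene was named from a probe set with several genes. Symbols were updated through the Entrez identifier with a RefSeq gene table, which matched 20351 probe sets; the remaining 29 kept the annotation's symbol. This gave 12393 genes, 4956 of them with 2 or more probe sets. A gene was represented by its probe set with the highest mean log2 signal, and it was called above background if any of its probe sets was. Of the 2319 genes above background with 2 or more probe sets, 1710 had at least 1 probe set that was not above background, so the calls of different probe sets of a gene often differed.

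Signals were floored at 1 and converted to log2. The background level of each array was the 95th percentile of the log2 signal over probe sets of gene families restricted to sensory neurons, adult glands, hair, germ cells and lymphocyte receptors, chosen by a name pattern. The pattern held 257 probe sets of 200 genes. It also took in 28 probe sets of 9 widely expressed genes, the casein kinases and interferon receptors, because their names begin like those of the caseins and alpha interferons. They raised the background level. The level as fixed was kept for the main calls, and the counts of called genes are also given for a lower level without these 9 genes, an alternative chosen after the data were seen. The main calls are therefore strict, and a gene not above background may still be transcribed.

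Detection was tested with limma (version 3.58.1, in R 4.3.3) as an intercept fit with lmFit and eBayes, with trend and robust options, on log2 signal minus the background level of the array. The test was one-sided, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The share of called genes in each of 28 gene lists was compared with all other genes by Fisher's exact test, two-sided, with adjustment over the 28 lists. The 200 background genes and the 4 measured sex-linked genes were left out of this comparison. Hox genes of paralog groups 1 to 5 were set against those of groups 9 to 13 with the same exact test. Genes and not samples are counted in these tests, and genes are not independent replicates. Variability between samples was tested over the 4287 genes whose mean lay above the background level, by an F test of each gene's variance against limma's robust trend of variance on signal, with adjusted p below 0.05. Joint deviation of a list was the SD over the 5 samples of the mean centred log2 signal of its members with a mean above the level, as a percentile among 10000 random lists matched on signal, for lists with at least 5 such members. The fixed wording asked for members above background; members with a mean above the level were used instead, which can include members the limma test did not call. It describes these samples and gives no p-value.

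Each step was tested on simulated data. In 20380 simulated probe sets, detection recovered 90% of those seeded 0.5 log2 units above the level and 100% at 1 and at 2 log2 units, with 0.0537% of calls false. Probe sets without excess kept their observed means, and the level was taken as known. The false share therefore leaves out any error in the level itself. In 4287 simulated genes, the variance test recovered 8% of genes with 3 times the usual SD and 73% with 6 times, with 0 false calls, so only very large differences between samples could be called. Of 400 simulated lists with no joint deviation 4.75% reached the 95th percentile, against 96% of 50 lists given a shared deviation with an SD of 0.25 log2 units. The simulated genes varied independently of each other, which genes on real arrays need not do.

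The tests, the gene lists, the rule for named genes and 19 alternatives were fixed before the data were examined. The rule named, per list, up to 4 called members with the highest signal over background and up to 3 members with the lowest, every member where 5 or fewer fell on 1 side, any Hox or sex-linked gene, up to 20 genes past the variance test with the largest ratio of variance to trend, and the 3 most variable members of the 3 lists with the highest joint deviation. The alternatives changed the normalization, the log offset, the choice of probe set, the background level, the detection rule, the filter on dim genes, the variance prior and the set of samples. A second added alternative kept the 13 control probe sets annotated with 1 mouse gene as probe sets of that gene. With 1 group and no other condition, no comparison between groups was possible, and the number of arrays limits the precision of every value. No batch could be tested: the labels mark no split of the 5 arrays. The p-values of the limma detection test measure the spread between these 5 isolates. Those of the F test set each gene's spread over the isolates against the trend. Those of Fisher's exact test rest on counts of genes and measure no spread between isolates.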

Results

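The series profiled 5 wild-type samples of pharyngeal arch tissue at E10.5 to ask which genes this tissue expresses. The pharyngeal arches are paired outgrowths beneath the embryonic hindbrain, built from neural crest, mesoderm, endoderm and ectoderm. The median signal per array was 29.0, 28.2, 28.1, 30.3 and 32.2 in replicates 1 to 5. The background level was a signal of 68.0, 90.7, 95.5, 107 and 96.6 in the same samples, and the lower level was 17.5, 16.4, 19.4, 24.2 and 23.6. Of 12393 genes, 3721 (30.0%) were above background, and 6625 (53.5%) were above the lower level. Signals below are means ± SD of the scaled units, with n = 5, and the excess over background is in log2 units with its SE. The arrays resembled each other to different degrees. Replicates 1 and 2 were closest, with a median absolute difference of 0.19 log2 units over 4287 genes, and replicates 1 and 4 were farthest apart, with 0.33. Pearson's r across genes, which are not independent replicates, ran from 0.932 to 0.975.

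The first question was which genes tied to cell populations of the arches left a signal. The tissue was measured whole, so a called gene does not show which cells its RNA came from. Of 24 measured second heart field genes, 4 were above background. They were Isl1, which encodes a LIM homeodomain factor of cardiac progenitors (1387 ± 223, excess 3.92 ± 0.16), the forkhead genes Foxc2 (358 ± 129) and Foxc1 (289.8 ± 67.5), and Mef2c (210.0 ± 26.0). Above the lower level there were 7, which added Tbx20 (107 ± 42.0), Tbx5 (52.5 ± 26.1) and Bmp4 (39.2 ± 6.83). Tbx1 (28.2 ± 10.9), Nkx2-5 (5.09 ± 3.35), Hand2 (8.24 ± 6.60), Fgf10 (13.4 ± 6.20) and Fgf8 (1.01 ± 0.384) were called at neither level. Each is long tied to outflow tract or arch development. Tbx1 lay above the lower level in replicates 1 to 3 (44.7, 31.6 and 25.6) but did not pass there (adjusted p = 0.140, limma). Of these genes Tbx20, Tbx5, Bmp4, Tbx1, Hand2 and Fgf10 are named outside the rule and were chosen after their values were seen. A probe set without signal can also be a probe set that binds poorly, so no absence of these transcripts follows.

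Among 26 measured genes of neural crest and arch mesenchyme, 7 were above background, with Crabp1, a retinoic acid binding protein (2740 ± 355, excess 4.91 ± 0.14), Prrx1 (1063 ± 216), Pax3 (683.3 ± 86.4) and Twist1 (566 ± 85.5) among them. Above the lower level there were 18. Epithelial genes were also present. Of 21 pharyngeal endoderm genes, 4 were above background, namely Sox2 (266 ± 84.3), Krt18 (232 ± 60.2), Cldn6 (213 ± 51.0) and Epcam (129 ± 26.9), and 10 were above the lower level. Of 15 surface ectoderm genes, 4 passed, namely Esrp1 (363 ± 149), Perp (181 ± 55.1), Trp63 (170 ± 62.4) and Grhl2 (164 ± 22.4), with 6 above the lower level. Sclerotome and somite genes gave 1 of 14, Pax3, which the crest list also holds, and 7 at the lower level. None of the shares of these 5 lists differed from that of all other genes, with adjusted p from 0.219 to 1 by Fisher's exact test, and with 0.0770 to 0.823 at the lower level.

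Few muscle genes were above background, though the share of none of the 3 muscle lists passed the test at the main level. Of 26 cardiac muscle genes, Actc1, cardiac actin (156 ± 24.1), and Myl4, an atrial light chain (134 ± 26.3), were above background, or 7.69% against 30.5% of other genes. Fisher's exact test gave an adjusted p of 0.0521, and 0.0222 at the lower level, where 7 members were called. The atrial light chain gene Myl7 (36.4 ± 21.2) and the troponin gene Tnnt2 (41.6 ± 11.9), chosen after their values were seen, passed only the lower level. Branchiomeric and skeletal muscle progenitors gave 1 of 16, Ebf3 (1134 ± 159), with 6 at the lower level (adjusted p = 0.162 and 0.426, Fisher's exact test). Smooth muscle gave 2 of 12, Acta2 (222 ± 58.7) and Mylk (157 ± 38.9), with 3 at the lower level (adjusted p = 0.604 and 0.197, Fisher's exact test). Endothelium gave 3 of 21, the receptors Tek (341 ± 43.5) and Flt1 (133 ± 30.9) and the surface protein Cd34 (134 ± 24.1), with 9 at the lower level (adjusted p = 0.389 and 0.534, Fisher's exact test).

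Genes of red blood cells and neurons were among those above background. Erythroid genes gave 6 of 20, a share of 30% against 30.5% of other genes (adjusted p = 1, Fisher's exact test), with 8 at the lower level (adjusted p = 0.477). The embryonic globins Hbb-y (5639 ± 705, excess 5.95 ± 0.13), Hbb-bh1 (4889 ± 1839) and Hba-x (1606 ± 733) were among them, with the transferrin receptor Tfrc (2118 ± 247). Of 25 genes of neural tube and neurons, 14 were above background, among them the stathmins Stmn3 (1463 ± 411, excess 3.97 ± 0.16) and Stmn2 (754.5 ± 209), the neurofilament gene Nefl (783 ± 170) and Dcx (658 ± 221). The adjusted p of this share was 0.0521 by Fisher's exact test, and at the lower level, with 18 called, it was 0.248. Leukocyte genes gave 1 of 20, Coro1a (166 ± 22.8), with an adjusted p of 0.0521 and, with 4 called at the lower level, 0.0123.

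Adult tissue markers and liver and yolk sac endoderm genes gave no calls at the main level. Of 37 adult tissue markers not known in the arches, 0 were above background (adjusted p = 2.94e-05, Fisher's exact test), and at the lower level Mbp (35.2 ± 11.3) was the 1 exception. Of 20 liver and yolk sac endoderm genes, 0 were above background (adjusted p = 0.00934), and 3 were above the lower level, namely Ttr (330.2 ± 198), Vtn (73.1 ± 16.8) and Apoa2 (64.6 ± 72.7). Mbp, Vtn and Apoa2 were chosen after their values were seen. Ttr lay above the main level in replicates 1, 2, 3 and 5 (349, 253, 507 and 508) and below it in replicate 4 (34.4). With a mean excess of 1.40 ± 0.75 it was not called, so a list without calls need not lack signal. Without replicate 4 the share for liver and yolk sac endoderm was 5.00% and the adjusted p 0.0525.

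**Figure D1:**
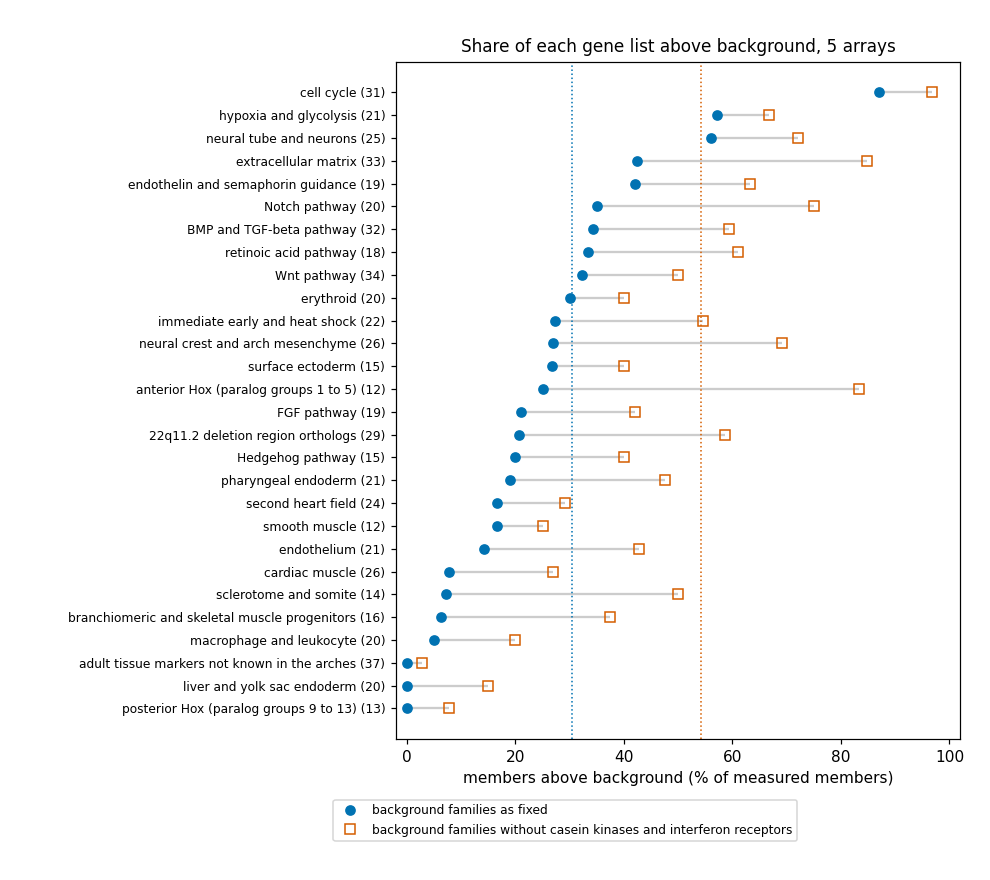
Share of the measured members of each of 28 gene lists above background (horizontal axis, percent; number of measured members in parentheses), with the background level as fixed (filled circles) and with the lower level (open squares). The dotted lines mark the share of other genes, 30.5% and 54.3%. Cell cycle genes stand highest on the filled circles with 87.1%, and posterior Hox genes, liver genes and adult tissue markers stand at 0.

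Hox genes mark position along the body axis, and anterior paralog groups are transcribed in the hindbrain and arches. Of 12 measured genes of groups 1 to 5, 3 were above background, Hoxc4 (319 ± 112, excess 1.75 ± 0.20), Hoxa3 (236 ± 52.8) and Hoxb4 (156 ± 52.3). Of 13 measured genes of groups 9 to 13, 0 were. The difference of 25.0 percentage points did not pass Fisher's exact test (p = 0.0957). At the lower level 10 anterior genes and 1 posterior gene, Hoxb9 (56.96 ± 32.9), were called, a difference of 75.6 percentage points (p = 0.000213, Fisher's exact test). Against all other genes the anterior share passed at neither level. It was 25% against 30.5%, and 83.3% against 54.2% at the lower level (adjusted p = 0.145, Fisher's exact test). The low posterior share passed at the lower level (7.69% against 54.3%, adjusted p = 0.00548, Fisher's exact test). The anterior genes Hoxd1 (19.6 ± 7.33) and Hoxc5 (14.8 ± 11.8) were called at neither level. Posterior Hox signal was uneven between the samples. Hoxd9 stood at 331 in replicate 2 and at 9.53 or less in the other samples.

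**Figure D2:**
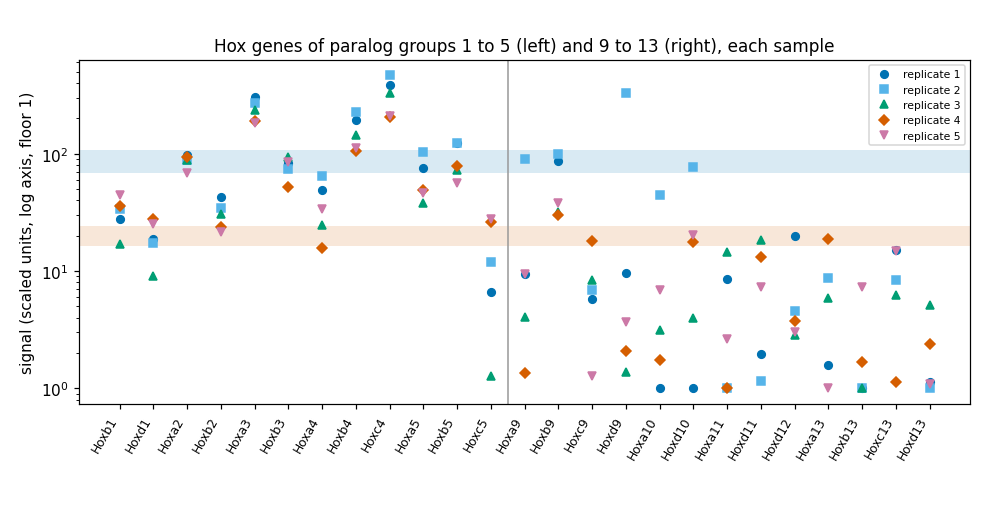
Signal of each measured Hox gene (vertical axis, scaled units on a log axis with a floor of 1) in each of the 5 samples (symbols), with paralog groups 1 to 5 left of the line and 9 to 13 right of it. The blue band spans the background level of the arrays, 68.0 to 107, and the orange band the lower level, 16.4 to 24.2. Hoxd9, Hoxa9, Hoxa10 and Hoxd10 stand apart in replicate 2.

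The second question was which signalling and matrix genes the tissue carried. Retinoic acid genes gave 6 of 18 above background and 11 at the lower level, with Crabp2 (3653 ± 867, excess 5.31 ± 0.13) and the nuclear receptors Nr2f2 (709.5 ± 306) and Nr2f1 (559.5 ± 93.3) beside Crabp1. FGF genes gave 4 of 19 (8 at the lower level), the receptor Fgfr2 (840.4 ± 161) and the feedback inhibitors Spred1 (477 ± 50.5), Dusp6 (462 ± 81.1) and Spry2 (301 ± 78.1). BMP and TGF-beta genes gave 11 of 32 (19 at the lower level), with the receptors Acvr2a (1360.1 ± 452) and Tgfbr1 (963 ± 131), the shared mediator Smad4 (819 ± 109) and the target Id2 (778 ± 158). Wnt genes gave 11 of 34 (17 at the lower level), with beta-catenin, Ctnnb1 (3653 ± 693), the coreceptor Lrp6 (803 ± 101), the receptor Fzd2 (702 ± 181) and the secreted Sfrp2 (1019.9 ± 640). Sfrp2 ranged from 354 in replicate 4 to 1798 in replicate 1. Hedgehog genes gave 3 of 15 (6 at the lower level), the receptor and target Ptch1 (3173 ± 318), Gas1 (660.0 ± 120) and Boc (590 ± 70.4). Notch genes gave 7 of 20 (15 at the lower level), with Notch2 (1639 ± 362), Nrarp (655 ± 106), Hey1 (484 ± 49.98) and Notch1 (363 ± 123). Guidance genes gave 8 of 19 (12 at the lower level), with the chemokine receptor Cxcr4 (865 ± 318), the semaphorin receptor Nrp1 (604 ± 74.4), Efnb2 (369 ± 136) and Epha3 (267 ± 85.0). None of these 7 lists differed from other genes in its share, with adjusted p from 0.594 to 0.955 by Fisher's exact test and from 0.197 to 0.787 at the lower level.

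Matrix genes gave 14 of 33 above background (42.4%, adjusted p = 0.395, Fisher's exact test). They included versican, Vcan (1506 ± 340, excess 4.03 ± 0.15), Sparc (1474 ± 303), Col3a1 (851 ± 91.8) and nidogen, Nid1 (385 ± 116). At the lower level 28 (84.8%) were called, more than the 54.2% of other genes (adjusted p = 0.00299). Mouse counterparts of the human 22q11.2 deletion region, whose loss causes arch and outflow defects, gave 6 of 29. Ranbp1 (1568 ± 132), Med15 (524 ± 114), Ufd1 (394 ± 75.9) and Mrpl40 (270.1 ± 20.03) were among them, and 17 were above the lower level. Tbx1, the gene of this region best known in arch development, was called at neither level.

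Proliferation genes stood out. Of 31 cell cycle genes, 27 (87.1%) were above background, against 30.3% of other genes (adjusted p = 2.44e-09, Fisher's exact test). The replication clamp Pcna (3701 ± 451, excess 5.35 ± 0.13), the reductase subunit Rrm2 (3684 ± 228), Ccnd2 (2433 ± 312) and Top2a (2358 ± 283) were among them. At the lower level 30 were called (adjusted p = 2.43e-06). Hypoxia and glycolysis genes gave 12 of 21 (57.1%, adjusted p = 0.0521) and 14 at the lower level (adjusted p = 0.477), with the glucose transporter Slc2a1 (3709 ± 875), Pgk1 (3268 ± 350), Ldha (2137 ± 375) and Aldoa (1357 ± 377). Immediate early and heat shock genes, which also respond to dissection, gave 6 of 22 and 12 at the lower level, with Hsph1 (4794 ± 490), Klf6 (630.3 ± 106), Jun (517 ± 158) and Dnajb1 (278 ± 31.5). Adjusted over the list alone, 24 of the 28 lists had the same number of called genes; cardiac muscle then had 1, retinoic acid genes 5, matrix genes 15 and cell cycle genes 28. In total 3 lists passed the adjusted Fisher's exact test (cell cycle, adult markers, liver), and 7 passed at the lower level. Another 5 lists, cardiac muscle, leukocytes, neurons, posterior Hox and hypoxia, shared the adjusted p of 0.0521, and all 5 passed when the control probe sets of mouse genes were kept, so their side of the threshold is not settled.

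The last question was where the 5 samples differed from each other. Genes of the sex chromosomes separated replicate 4. Xist, the RNA that coats the inactive X chromosome of female cells, gave 916 in replicate 4 and 26.3 or less in the other samples, and its other probe sets gave 992 and 1595 in replicate 4. The Y-linked gene Eif2s3y gave 20.1 in replicate 4 and 769 to 968 elsewhere. Kdm5d, also Y-linked, gave 17.5 in replicate 4 and 120.4 to 201 elsewhere. Uty, with 12.1 in replicate 4 and 20.7 to 38.8 elsewhere, was called at neither level.

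Of 4287 genes, 5 varied between the samples by more than genes of like signal (adjusted p below the threshold in the F test against limma's trend), and 220 did so at an unadjusted p below 0.05. They were Eif2s3y, with a variance 74.8 times the trend (adjusted p = 0.00131), Ctr9 (50.1 times, adjusted p = 0.00414), Gm6958 (43.2 times), Ttr (30.6 times) and Erdr1 (26.6 times). Only Eif2s3y was represented by a probe set whose name ends in plain _at. The names of the others end in _s_at (Ctr9) or _x_at, and with plain probe sets alone only Eif2s3y passed. Ctr9, a subunit of the Paf1 elongation complex, gave 56.4 in replicate 3 and 828 to 1152 elsewhere. Its other 3 probe sets, with mean signals below the background level, were not low in replicate 3. The brightest of them had its highest signal there (97.9). Gm6958 gave 69.1 and 80.0 in replicates 4 and 5 and 374 to 1161 in the other samples, and its second probe set was low in the same samples. Ttr, which encodes the thyroxine carrier transthyretin, gave 34.4 in replicate 4 and 253 to 508 elsewhere, with all 3 probe sets lowest in replicate 4. Erdr1 gave 435 in replicate 2 and 4203 in replicate 4, against 1568 to 1791 in the others. With the lower level Mageh1 joined them, with 4.55 in replicate 1 and 98.2 to 124 elsewhere. The number of genes depended on single samples: it was 9 without replicate 2, 3 without replicate 4 and 2 without replicate 5.

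**Figure D3:**
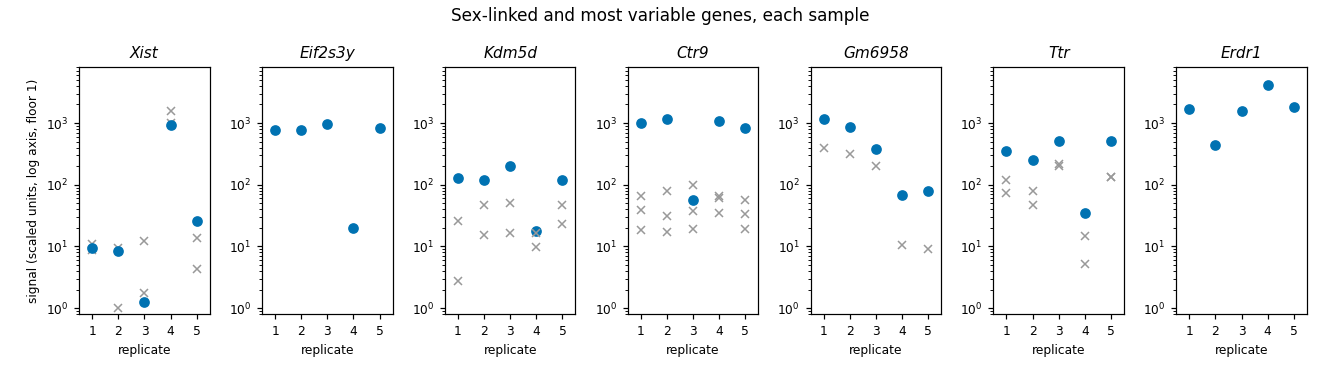
Signal in each of the 5 samples (horizontal axis, replicate number; vertical axis, scaled units on a log axis with a floor of 1) for 2 Y-linked genes, Xist and the other 4 genes past the variance test. Filled circles are the probe set that represents the gene, and crosses its other probe sets. Xist stands at 916 and Eif2s3y at 20.1 in replicate 4.

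The mean signal of some gene lists also differed between samples by more than that of random lists. The measure is the spread of a list's mean, so 1 very variable member can carry it. In the Wnt list (percentile 97.72) Sfrp2 had an SD of 0.99, and 2 of 11 members were lowest in replicate 4. Of 16 lists with at least 5 members bright enough, 9 deviated more than 95% of 10000 random lists of like signal. With the mean of all probe sets 4 did, and at the lower level 10 of 24 did. There hypoxia (94.28) and immediate early genes (93.82) fell short, and the 22q11.2 list rose from percentile 79.32 to 99.32. Genes of neural tube and neurons had the highest percentile at the main level (99.97), though not the largest SD, which was 0.26 against 0.32 for erythroid genes. Their mean was 0.43 log2 units below the average of the samples in replicate 4 (-0.43), where 11 of the 15 members had their lowest value, and it was 0.23 above in replicate 3. Ina (SD 0.73), Nefm (SD 0.48) and Nhlh1 (SD 0.47) varied most. Erythroid genes followed (percentile 99.71), with -0.39 in replicate 4 and 0.42 in replicate 5. In replicate 4, 3 of the 6 members were lowest and 1 was highest, with Hba-x at -1.53 and Hbb-bh1 at -0.63. Hba-x (SD 0.90), Hbb-bh1 (SD 0.52) and Car2 (SD 0.51) varied most, and Hba-x ran from 490 in replicate 4 to 2471 in replicate 5. Matrix genes came next (percentile 99.35), with 0.20 in replicate 1 and -0.25 in replicate 4, led by Col4a2 (SD 0.55), Col5a2 (SD 0.44) and Nid1 (SD 0.42). Without replicate 4 the percentile of the neural list was 92.05, and without replicate 1 that of the matrix list was 91.23. The matrix list also fell short of the 95th percentile at the lower level (88.83) and with the mean of all probe sets (93.03). Second heart field genes (percentile 24.24), BMP and TGF-beta genes (15.95) and cell cycle genes (70.75) did not deviate jointly.

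**Figure D4:**
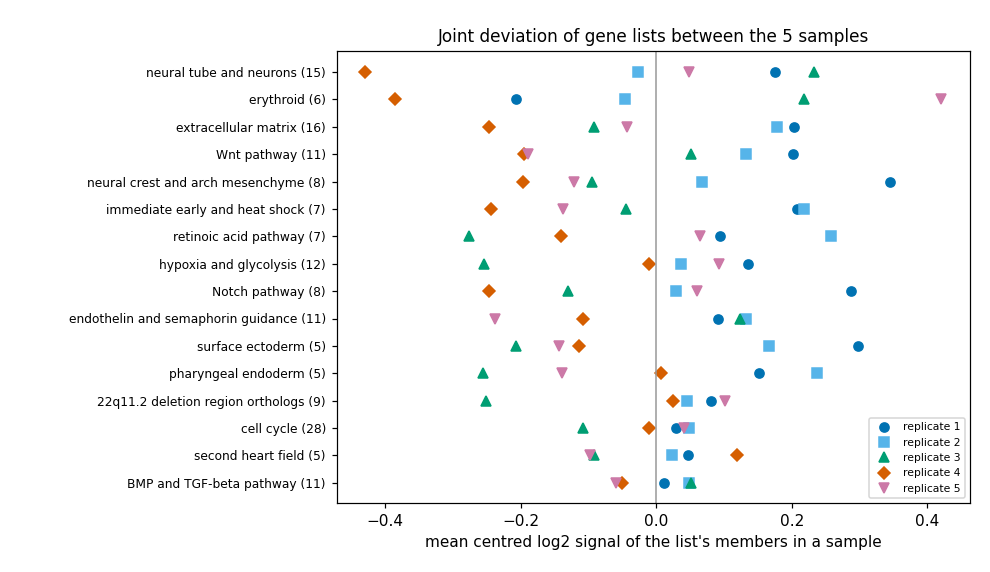
Mean centred log2 signal of the members of each of 16 gene lists (horizontal axis, log2 units; number of members in parentheses) in each of the 5 samples (symbols), ordered by percentile among random lists, highest at the top. The neural list stands at -0.43 in replicate 4 and the erythroid list at 0.42 in replicate 5.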

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

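The tests of an array-wide effect, of 5′ loss, of globin probe sets, of the Ctr9 probe sets, of the other lists in replicate 4 and of the spread in the second erythroid list were chosen after the results were seen; the second neuron list, the second erythroid list and the chromosome neighbours were set up before theirs. Of 138 values tested for a sample that stood far from the other 4, 12 did. Chance gives about 5%, but some of these genes were named because they varied, so the count is no test. Eif2s3y was lower in replicate 4 by -5.38 log2 units than the mean of the other samples, and Kdm5d by -2.998. Ttr was lower in replicate 4 by -3.50 and Nefm by -1.07, while Esrp1 was higher there by 1.08. Ctr9 was lower in replicate 3 by -4.17, Ldha by -0.61, and the mean of the 22q11.2 list by -0.31, while Epha3 was higher in replicate 3 by 0.87. Hoxa2 was lower in replicate 5 by -0.42, Hoxb13 higher there by 2.67 and Hoxd12 higher in replicate 1 by 2.52, the last 2 at signals near the floor. Among the 2246 probe sets with several genes or none, which no comparison used, 559 were above background.

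The neural list was low in replicate 4, the sample with Xist signal. An array effect cannot be told apart: the mean of -0.43 lay below all 10000 matched random lists there (percentile 0), but the list and the sample had been picked for this deviation, and 18S RNA (4463) and the 3′ probe set of Actb (3135) were highest in replicate 4. Less neuronal RNA in the tissue cannot be told apart either: a second list of 13 neuronal genes, none of them in the first, had a mean of -0.30 (percentile 0.33), but 12 of 15 other lists were below 0 too, and erythroid (percentile 0.53) and matrix genes (0.93) were about as low among matched random lists. Greater loss of 5′ sequence cannot be told apart: the ratio of 3′ to 5′ signal in replicate 4 was 4.82 for Actb, the highest of the samples, but 2.89 for Gapdh, within their range. High Xist with low Eif2s3y and Kdm5d marks the tissue of replicate 4 as female, and the other samples had the reverse, as in males. Whether sex bears on the neural list stays open and untested, since no second sample had Xist signal.

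Ctr9 and the highly variable genes of the autosomes gave 2 explanations to weigh. For Ctr9, a change confined to 1 probe set cannot be told apart from less transcript. The other 3 probe sets differed in replicate 3 from the other samples by 0.12 log2 units on average, but their mean signals lay below the background level. The brightest of them was highest in replicate 3 (97.9, against 56.9 to 78.1 elsewhere), and the next gave 38.2, within 31.7 to 66.2. Both lay above the lower level in every sample and gave no sign of less transcript. They were far dimmer than the first probe set, and replicate 3 is 1 array, so less transcript stays open. Segregating 129P2/OlaHsd and C57BL/6 segments could make neighbouring genes vary together. Among 197 highly variable autosomal genes, pairs within 100 genes of each other had a mean profile product at percentile 92.43 of shuffled positions. Pairs within 50 genes gave 99.22 and pairs within 200 gave 86.30, so this explanation cannot be told apart from chance. No group in the design offers a biological explanation to test.

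The erythroid list differed between samples. Different amounts of blood were tested with a second erythroid list, whose deviations followed the first list's at percentile 80.56 with 5 genes and 93.86 with 17 genes at the lower level. Both fell short of the bound set beforehand. Added to random lists, a shift as large as that of the first list passed in 99.72% and 99.99% of them. A shift 0.5 times as large passed in 71.08% and 81.96%. This counts against a full shift of every gene, but genes also transcribed outside blood need not show the full shift. At the lower level the 17 genes were lowest in replicate 4 (-0.15) and highest in replicate 5 (0.13), as the first list was (-0.30 and 0.36). In replicate 1 they went the other way (0.03 against -0.30). The 5 genes were highest in replicate 5 (0.13) but lowest in replicate 3 (-0.10). The bound made no allowance for spread between genes. The value of the 17 genes missed it by only 0.39 of its SD over genes (1.22 for the 5 genes), so different amounts of blood cannot be told apart from none. Cross-hybridisation between globin probe sets cannot be told apart either: the 3 members of the list that are not globins followed the 3 globins at percentile 88.74.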

How the results depend on the processing

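The setting without casein kinases and interferon receptors and the one that kept the control probe sets of mouse genes were added after the data were seen; all others were planned. The count of 3721 genes above background lay between 3585 and 3796 without each replicate and was 3719 after quantile normalization, of which 3718 were shared. It depended on the background level, with 5730 at the 90th percentile of the families, 672 at the 99th, 7418 with non-mouse controls, 6794 with the 40th percentile of all probe sets and 6625 without the kinases and receptors. The higher share of cell cycle genes passed in every setting, and the lower share of adult markers in all but the 99th percentile (0%, adjusted p = 1). The lower share of liver genes was also lost there (0%, adjusted p = 1), with the mean of all probe sets (0%, adjusted p = 0.0752) and with plain probe sets only (0%, adjusted p = 0.0906), and ranged from 0% to 5.00% without each replicate. Lists past the threshold numbered 3 in the main setting, 5 at the 90th percentile, 1 at the 99th, 7 with non-mouse controls, with the 40th percentile and without the kinases and receptors, 8 with the control probe sets kept, and 3 to 8 without each replicate. Fisher's exact test for anterior against posterior Hox genes passed with differences of 50.6 percentage points at the 90th percentile and 75.6 with non-mouse controls, the 40th percentile and the families without kinases. Cardiac muscle passed with 11.5% at the 90th percentile, 26.9% at the 40th percentile of all probe sets and without kinases, 3.85% when each array had to be above the level, and 7.69% with control probe sets kept. Posterior Hox genes passed with 7.69% in the 90th and 40th percentile settings, with non-mouse controls and without kinases, and with 0% with control probe sets kept. Leukocyte genes passed with 30% with non-mouse controls, 20% with the 40th percentile and without kinases, and 5.00% with control probe sets kept; matrix genes with 90.9%, 84.8% and 84.8% in the first 3 of these, and Notch genes with 90% with non-mouse controls. Neural genes passed with 56% with plain probe sets and with control probe sets kept, and hypoxia genes with 59.1% in the latter. Without each replicate, neural genes ranged from 56% to 60%, cardiac muscle from 3.85% to 7.69%, leukocyte genes stayed at 5.00%, posterior Hox at 0% and hypoxia genes at 57.1%, each passing in at least 1 of the 5. Variable genes numbered 1 with plain probe sets (Eif2s3y), 21 without a filter on dim genes, of which 5 were the main ones, 3 with a prior without a trend, and 2 to 9 without each replicate. Lists with joint deviation numbered 4 in place of 9 with the mean of all probe sets. The matrix list's percentile was 93.03 there and 88.83 without kinases, and 91.23 to 99.54 without each replicate; the neural list's was 92.05 to 100 without each replicate. Apart from the background levels, whose construction sets how many genes pass, and from fewer samples or probe sets, the cause was not tested. No paired analysis was possible because there was 1 group. Signal over background limits what can be called: in simulation 90% of probe sets 0.5 log2 units above the level were recovered, and smaller excesses were not simulated.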

Other observations

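The tests of posterior Hox and limb bud genes and the counts for liver genes were chosen after the values were seen, and Afp, Apoa1, Ambp and Rbp4 are named outside the rule. Liver and yolk sac genes were dim, but they were highest in 1 sample. Of 20 measured genes, 17 had their highest signal in replicate 5, against 26.3% of all genes and a maximum of 14 among 10000 random lists matched on signal. Afp, the fetal serum protein alpha-fetoprotein, gave 198 in replicate 5 and 20.7 or less elsewhere. Apoa2 gave 194 in replicate 5 and 47.4 or less elsewhere, Apoa1 67.4 against 34.1 or less, Rbp4 53.4 against 20.7 or less, and Ambp 40.2 against 6.83 or less. Erythroid genes were highest in the same sample.

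Posterior Hox genes were seen in replicate 2. Hoxd9 gave 331 there and 9.53 or less elsewhere, Hoxa9 90.1 against 9.42 or less, Hoxd10 77.1 against 20.3 or less, and Hoxa10 44.6 against 6.86 or less. Hoxb9 gave 86.0 and 98.9 in replicates 1 and 2 and 38.1 or less elsewhere. Hoxa11, Hoxd11, Hoxd12, Hoxa13 and Hoxd13 gave 8.72 or less in replicate 2. At the lower level anterior Hox genes deviated jointly too (percentile 99.86), with means of 0.32 and 0.41 log2 units in replicates 1 and 2 and -0.16 to -0.34 in the others. At the same level other lists past percentile 95 were also above 0 in replicates 1 and 2, by less than the Hox genes. They were retinoic acid (0.23 and 0.25, percentile 99.76), Wnt (0.21 and 0.12, percentile 95.32), neural crest (0.30 and 0.02), 22q11.2 (0.15 and 0.07) and neural genes (0.12 and 0.03). Erythroid and cardiac muscle genes were below 0 in both samples, and leukocyte and Notch genes only in replicate 2. The rise was thus not particular to Hox genes, and these 2 arrays were the closest pair.

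A hypothesis is that the piece dissected for replicate 2 may have included tissue from farther back, such as forelimb bud. Noise of dim probe sets cannot be told apart: 4 of 13 posterior Hox genes were at least 1 log2 unit higher in replicate 2 than in every other sample, against 0.960% of all genes, above 99.98% of random lists matched on signal, but the list, the sample and the bound had been picked from these values. The same count was 1, 1, 2 and 1 in replicates 1, 3, 4 and 5, against 1.09%, 1.46%, 2.32% and 3.07% of all genes. A list of 13 limb bud genes, written after the Hox values had been seen, was high in replicate 2 (0.36 log2 units, percentile 99.99 among matched random lists), as were the 8 of them in no other list (percentile 100). It was high in replicate 1 as well (0.32, percentile 99.55), where Hoxd9 and Hoxa9 gave 9.53 and 9.34. In replicate 2 its members Msx1, Jag1 and Prrx2 were below their own means (-0.06, -0.15 and -0.14), and the rest were above theirs. Of these 13 genes 5 are in lists of arch tissue or signalling, and Irx3, Tbx3 and Meis1 are also known outside the limb, so limb bud cannot be told apart from other posterior tissue or from mesenchyme shared with the arches.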
